A study of Homo sapiens with 32 samples.

How the data were processed

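The values used were log2 gene-level intensities of transcript clusters on a human exon array, as deposited by the authors, with 1 column per array and no missing value. A transcript cluster is the set of probes that the array assigns to one gene. Per the labels, cells were given 200 µM 4-thiouridine (4sU) for 2 h, total RNA was isolated, the 4sU-labelled nascent RNA was separated from it, ribosomal RNA was reduced, and labelled cDNA was made with Affymetrix whole-transcript kits. The submitters' processing notes name Affymetrix Power Tools and genome build hg18. The summary algorithm, the background correction, the version of the tools and whether nascent and total RNA arrays were normalized together are not given in the sources used here. Array medians lay between 6.74 and 6.95 in total RNA and between 7.58 and 7.93 in nascent RNA, so a ratio of both can be read only relative to other clusters of the same culture. No half-life in hours is given for this reason.

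Of 21788 clusters, 34 that belong to sex-linked genes were left out before anything else, which left 21754. Gene symbols came from the platform's table of clusters and genes: 14405 clusters had exactly 1 symbol, 2365 had several and 5018 had none. The current symbol was looked up in a RefSeq gene table for 14377 of the 14405. Background was the 95th percentile of the mean log2 value of 216 olfactory receptor clusters, genes of the nasal epithelium, which was 6.40. Clusters whose mean over all 32 arrays was above it were tested: 14155 clusters, of which 9630 had 1 symbol, 1507 several and 3018 none. Only clusters with 1 symbol are named.

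The nascent/total ratio of a culture was its nascent minus its total log2 value. Technical duplicates were averaged first, and each culture was then centred on its median over the 14155 clusters. A positive value therefore means more newly made RNA relative to total RNA than in the median cluster of the same culture. Over 7 lines, 1 value per line (the mean of its cultures) was tested against 0 with limma (lmFit and eBayes with a trend, two-sided). Between GM07029, GM10835 and GM12813, the 9 cultures were compared with limma's moderated F test for the ratio, for total RNA and for nascent RNA, and the 3 pairwise contrasts came from the same fit. Adjusted p is by Benjamini and Hochberg over the clusters tested, and the threshold was 0.05. Where a gene or list is said to be higher, lower, to have risen or fallen, it passed this threshold.

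Gene lists were fixed before the data were examined, as were the samples, the tests, the rule for named genes and most of the alternative settings; the settings added later are named as such, and the list test in nascent RNA was added later. The lists were immediate early genes, NF-kB targets, cytokines and chemokines, KRAB and other C2H2 zinc finger genes, cytosolic and mitochondrial ribosomal proteins, oxidative phosphorylation, glycolysis, the proteasome, tRNA synthetases, translation factors, replication-dependent histones, mitotic genes, DNA replication genes, small nucleolar RNA hosts and nuclear noncoding RNAs, p53 targets, heat shock and unfolded protein response, interferon-stimulated genes, cholesterol and fatty acid synthesis, B cell identity genes, plasma cell genes, HLA class II genes, markers of T and NK cells, of monocytes and granulocytes and of fibroblasts and epithelia, and mRNA decay factors. Families were matched by symbol pattern, so that a few members are relatives by name only. The 25 lists with at least 3 tested members went through limma's camera with a preset correlation of 0.01 between genes, with the Benjamini-Hochberg adjustment over lists (and over contrasts of a measure), and again with the correlation estimated from the data. fry, which tests whether the genes of a list move on balance one way, was run beside it over 7 lines.

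The rule for named genes took clusters with 1 symbol, leaving out olfactory receptors and immunoglobulin and T cell receptor segments, and the cluster with the highest mean where a gene had several. For the ratio over 7 lines it took the 12 highest and 12 lowest means among clusters past the threshold with the same sign in all 7 lines, and the 3 members of each list with the largest absolute mean past the threshold (the 2 largest where none passed). Between 3 lines it took the 24 largest ranges of line means for the ratio, 20 for total RNA and 10 for nascent RNA, and for each called list and contrast the 3 members with the largest difference past the threshold. MYC, FOS, JUN, NFKBIA, MCL1, ACTB, GAPDH, RPLP0, EEF1A1 and TUBB were to be named whatever their values, but MCL1, GAPDH, RPLP0 and EEF1A1 had no cluster with a single symbol.

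Simulated data of 14155 genes with the replication of each comparison were put through the same steps. Of genes given a log2 difference of 0.5, 1 and 2, the test over 7 lines called 49.3%, 86.6% and 100%. The ratio between 3 lines gave 20.9%, 73.1% and 98.5%, total RNA 35.8%, 82.1% and 98.5%, and nascent RNA 62.7%, 94.0% and 100%. Among 13955 genes simulated without a difference, the same tests called 4, 6, 7 and 7. Few simulated genes were given a difference, and noise was drawn for each gene independently. In the data many more clusters were called and genes may vary together, so these rates need not carry over. R 4.3.3 and limma 3.58.1 were used. The relation of the ratio to gene features and to sequence variants, which the series' design also names, was not analysed here.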

Results

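RNA was measured in 7 B-lymphoblastoid cell lines, which are B cells of HapMap donors made to grow without limit by Epstein-Barr virus. Each culture was given the nucleoside 4-thiouridine for 2 h, so that RNA made in that time carried the label, and the labelled (nascent) RNA and the total RNA of the same culture went onto separate exon arrays. There were 32 arrays, 16 of total and 16 of nascent RNA, from 13 cultures. GM07029, GM10835 and GM12813 were grown as 3 independent cultures each, and GM07019, GM12812, GM12814 and GM12815 as 1 culture each. Each GM12813 culture was also hybridized again as a technical duplicate in both fractions. The series set out to measure mRNA stability from the ratio of nascent to total RNA and to ask which genes differ in it between people. In that reading, a transcript that is replaced quickly has a high ratio, and one that turns over slowly a low ratio. The ratio was not related here to transcript length or number of uridines, so a low ratio does not by itself show slow turnover. All ratios below are log2 values relative to the median cluster of the culture, and the number of arrays limits their precision. Of the transcript clusters, 14155 (65.1%) lay above background and were tested.

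Total RNA profiles of cultures of one line had a mean Pearson correlation across clusters of 0.978, and those of different lines 0.938. For nascent RNA these values were 0.990 and 0.948. The ratio, which carries the noise of both arrays, had a mean correlation of 0.911 between technical duplicates, 0.900 between cultures of a line and 0.797 between lines. Clusters are not independent replicates. The median standard deviation (SD) of the ratio over clusters was 0.130 log2 units between technical duplicates and 0.154 between cultures of a line. It was 0.261 between the 7 lines. These SDs rest on pairs, on 3 cultures and on 7 lines, and a median SD from fewer values runs lower. Part of the rise therefore comes from the number of values, and duplicates cannot be said to vary less than cultures. Cultures of GM07029 varied more (0.216) than those of GM10835 (0.127) and GM12813 (0.120), and without its technical duplicates GM12813 gave 0.195. The first total RNA array of GM12813 replicate 3 had the lowest mean correlation with its own line (0.960), and among nascent arrays that of GM12815 had the lowest with other lines (0.919).

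The first comparison asked which transcripts had a high or a low share of newly made RNA in all lines. Among the 12 highest ratios, PNN, a protein of nuclear speckles, had a mean ratio of 3.86 ± 0.58 (SD, n = 7 lines), the transcription factor ZNF143 2.97 ± 0.14, and ZC3H13, of the complex that methylates adenosines in mRNA, 2.94 ± 0.30. Mean total RNA of ZNF143 (5.28), ZC3H13 (5.68), AMMECR1L (5.93), MRFAP1L1 (6.34), TEX30 (4.51) and URGCP (5.33) lay below the background of 6.40, so their ratios can be read as high but not ranked. The spliceosome proteins MFAP1, DDX23 and IK followed with 2.85 ± 0.25, 2.76 ± 0.40 and 2.75 ± 0.39. AMMECR1L (3.10), MRFAP1L1 (3.08), TEX30 (2.80), URGCP (2.80), MRFAP1 (2.67) and SAT1 (2.64), the enzyme that acetylates polyamines, completed the 12 highest. Among the 12 lowest, CD52, a small glycoprotein of lymphocytes, stood at -2.24 ± 0.14, the IgE receptor FCER2 (CD23) at -2.04 ± 0.12 and the complement receptor CR1 at -2.04 ± 0.31. The aldolase ALDOC stood at -2.01 ± 0.21, the respiratory complex II subunit SDHC at -2.17 ± 0.87, and EIF3E and EIF3L, subunits of an initiation factor, at -2.13 ± 0.29 and -1.99 ± 0.31. SH3BGRL had the lowest mean (-2.44 ± 0.18), and the antiviral deaminase APOBEC3H (-2.29), the kinetochore protein CENPH (-2.10, with mean nascent RNA of 5.80, below background), the oxidase of the endoplasmic reticulum ERO1A (-2.03) and NDRG3 (-2.01) were also among the 12 lowest. These 24 genes had the same sign in all 7 lines, with adjusted p from 4.83e-07 to 2.11e-05 (SDHC), and adjusted p = 9.38e-07 for PNN.

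In all, 8989 of 14155 clusters differed from the median cluster, 4495 of them higher and 4494 lower, and 7007 had the same sign in every line. Of these calls, 1301 were at least 2-fold above and 839 at least 2-fold below. A further 436 clusters had an unadjusted p under 0.05 without passing the threshold. Higher and lower hold only relative to the median cluster. Without centring, the median of all clusters was 0.77, and 12390 clusters were called, 93.8% of them higher.

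Of the lists, immediate early and zinc finger genes were called higher. Of 32 tested immediate early genes, which cells switch on within an hour of a stimulus, 21 were higher and 1 lower, with a median ratio of 0.39 (adjusted p = 0.000737, and adjusted p = 0.923 with an estimated correlation). The counts were the same adjusted over the list alone. IER2 stood at 2.01 ± 0.32, the stress-induced factor ATF3 at 1.89 ± 0.29 and PPP1R15A at 1.51 ± 0.33. The growth regulators MYC (0.70 ± 0.35, adjusted p = 0.000302) and JUN (0.71 ± 0.30, adjusted p = 0.000139) were higher, while FOS had a ratio of 0.14 that did not pass the test (adjusted p = 0.183). Of 266 tested zinc finger genes, mostly repressors of transcription, 97 were higher and 42 lower (90 and 41 adjusted over the list alone), with a median of 0.11 (adjusted p = 0.0418, and adjusted p = 0.937 with an estimated correlation). ZNF143, ZNF263 (2.14) and ZNF671 (2.06) were among the higher ones, all 3 with mean total RNA below background. By line the zinc finger median ran from -0.17 in GM12812 to 0.49 in GM10835. With the trend of the ratio with signal removed, a setting added after the data were seen, the zinc finger call ended (median 0.04, adjusted p = 0.330).

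The other 7 called lists were lower. Glycolysis had the lowest median of any list, -1.21, with 11 of 14 enzymes lower and 2 higher (adjusted p = 0.000737, and 0.797 with an estimated correlation). ALDOC and the enolase ENO2 (-1.66) were lower, and the hexokinase HK1 (1.65) was one of the exceptions. Of 55 genes of oxidative phosphorylation, 29 were lower and 9 higher (median -0.41, adjusted p = 0.0104, and 0.923 with an estimated correlation), among the lower ones SDHC, NDUFB5 (-1.34) and ATP5F1C (-1.27). Cytosolic ribosomal proteins had 12 lower and 3 higher members of 23 (median -0.42, adjusted p = 0.0391, and 0.923 with an estimated correlation). RPL11 (-1.60), RPS24 (-1.57 ± 1.22, with a wide spread between lines) and RPL18 (-1.45) had the largest ratios in absolute size among those called. Mitochondrial ribosomal proteins had 28 lower and 11 higher members of 63 (median -0.22, adjusted p = 0.0448, and 0.923 with an estimated correlation), from MRPL37 (-1.47) to MRPS31 (1.39) and MRPL27 (1.36). Of 33 proteasome subunits, 19 were lower and 5 higher (20 and 6 adjusted over the list alone), with a median of -0.39 (adjusted p = 0.0364, and 0.923 with an estimated correlation). PSMB6 stood at -1.82, PSMB2 at -1.40 and PSMC3 at 1.18. Medians of these lists varied between lines and came near 0 in some. Oxidative phosphorylation ran from -1.23 in GM10835 to -0.05 in GM12812, and cytosolic ribosomal proteins from -0.83 to -0.06 in the same lines. Mitochondrial ribosomal proteins ran from -0.47 in GM10835 to 0.01 in GM12814, and the proteasome from -0.60 to -0.13 in those lines.

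Replication-dependent histones, whose mRNAs end in a stem-loop in place of a poly(A) tail, had 34 lower and 6 higher members of 44, with a median of -0.81 (adjusted p = 0.000286, and 0.923 with an estimated correlation). H4C1 stood at -1.85 ± 0.40 and H2AC8 at -1.83 ± 0.38, whereas H2BC11 stood at 1.71 ± 0.29. Of 7 HLA class II genes, which present antigen to helper T cells, 6 were lower and 1 higher (median -1.11, adjusted p = 0.0391, and 0.797 with an estimated correlation). They included HLA-DOA (-1.47), HLA-DPA1 (-1.46 ± 0.09) and the chaperone CD74 (-1.25). None of the 9 list calls held with an estimated correlation. Without centring, only glycolysis (-0.43), histones (-0.04) and HLA class II (-0.34) kept a median below 0. With the trend with signal removed, the calls of the proteasome (median -0.31, adjusted p = 0.109) and of HLA class II (median -0.52, adjusted p = 0.363) ended. The histone median shrank to -0.43 in that setting.

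The remaining 16 lists did not pass. B cell identity genes came closest, with 16 lower and 5 higher of 27 (median -0.32, adjusted p = 0.0501), led by FCER2, CD79A (-1.97) of the B cell receptor and MS4A1 (-1.96), which encodes CD20. Plasma cell genes had 8 lower and 2 higher of 16 (median -0.33, adjusted p = 0.0713), with PDK1 at -1.71, JCHAIN at -1.68 and the plasma cell regulator PRDM1 at 1.17. NF-kB targets were split, with 10 higher and 10 lower of 26 (median -0.00, adjusted p = 0.881): TNF stood at 1.58 ± 0.36 and TNIP1 at 1.27, EBI3 at -1.29, and the inhibitor NFKBIA at -0.08 (adjusted p = 0.475, not passed). Cytokines and chemokines had 7 higher and 6 lower of 17 (median -0.06, mean 0.11, adjusted p = 0.881), LTB being higher and LTA lower (-0.92). Translation factors had 15 lower and 9 higher of 34 (median -0.14, adjusted p = 0.258), from EIF3E and EIF3L to EIF5B (1.80). The tRNA synthetases had 8 lower and 5 higher of 17 (median -0.13, adjusted p = 0.681), with QARS1 at -1.51, CARS1 at 1.42 and WARS1 at -1.18. Interferon-stimulated genes had 14 lower and 5 higher of 30 (median -0.15, adjusted p = 0.258), with OAS2 at -1.23, EPSTI1 at -1.20 and IFIH1 at 1.00. The p53 targets had 9 higher and 7 lower of 20 (median 0.00, adjusted p = 0.780), the higher ones led by XPC (1.94), SESN1 (1.77) and TNFRSF10B (1.72), with the mean total RNA of SESN1 (5.21) below background.

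Mitotic genes had 13 lower and 8 higher of 26 (median -0.14, adjusted p = 0.681), with KIF2C at 1.67, BUB1 at -1.35 and AURKB at 1.25. DNA replication genes had 13 lower and 8 higher of 25 (median -0.20, adjusted p = 0.669), with POLE at 1.49, POLE2 at -1.28 and MCM3 at 1.23. Heat shock and unfolded protein response genes had 7 higher and 8 lower of 20, and their median (0.05) and the test (down, adjusted p = 0.925) differed in sign. DNAJA1 (1.60) and HSPA5 (1.58) stood against CALR (-1.20). Cholesterol and fatty acid synthesis had 8 lower and 5 higher of 19 (median -0.12, adjusted p = 0.669), with SCD at -1.25, LSS at -0.94 and ACACA at 0.70. Among 43 mRNA decay factors, 17 were higher and 12 lower (median -0.02, mean 0.11, adjusted p = 0.673), with LSM1 at 1.64, the nonsense-mediated decay helicase UPF1 at 1.13 and the decapping factor DCP1A at 1.13. The signs of the tRNA synthetase, NF-kB and decay factor medians turned with the trend removed (0.15, 0.27 and 0.07). Of the noncoding RNA list only MALAT1 (-0.37, adjusted p = 0.0288) and TUG1 (-0.30, adjusted p = 0.0133) were measured, and both ratios turned positive without centring (0.40 and 0.47) and with the trend removed (0.25 and 0.07). The MALAT1 call also ended without GM07029, GM10835 or GM12813 (adjusted p = 0.0920, 0.0692 and 0.0787). The cytoskeletal genes ACTB (-0.81) and TUBB (-0.76) were lower, but with the trend removed neither was (adjusted p = 0.361 and 0.720), and without centring TUBB stood at 0.01.

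Markers of other cell types were mostly under background: 7 of 24 T and NK cell markers, 3 of 17 monocyte and granulocyte markers and 7 of 18 fibroblast and epithelial markers on the array could be tested. Their medians were -0.15, -0.02 and -0.02 (adjusted p = 0.452, 0.881 and 0.881). Of the first list 3 were lower (LCK at -0.88 and CD6 at -0.40 among them) and 1 higher (PRF1 at 0.23). Of the second 1 was lower (MNDA at -0.30; 0 adjusted over the list alone), and of the third 1 was higher (COL1A1 at 0.29) and 1 lower (MUC1 at -0.26). CD6, MNDA and MUC1 turned positive without centring (0.38, 0.48 and 0.52), and LCK no longer passed (adjusted p = 0.352). The PRF1 call ended with quantile normalization (adjusted p = 0.0723), with the trend removed (0.166) and without any 1 of 6 lines, and the MNDA call with no filter (0.0588), with 13 cultures (0.0601) and without any 1 of 5 lines. Counts of the other lists were the same adjusted over the list alone as over all clusters, except where both are given. The plot of list medians by line shows the 7 lines for each of the 25 lists.

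**Figure D1:**
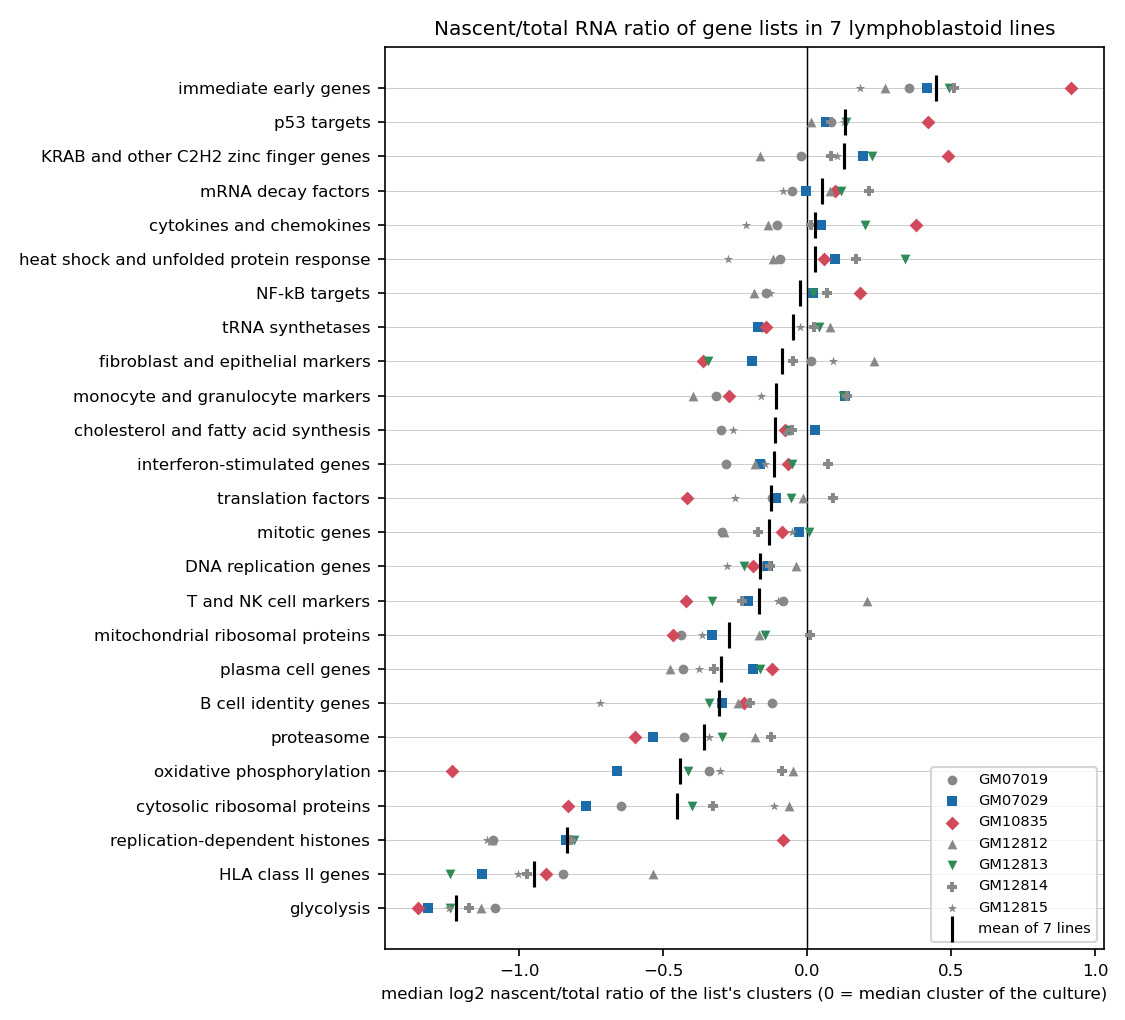
Median log2 nascent/total ratio (horizontal axis, relative to the median cluster) of the tested members of 25 gene lists (vertical axis) in each of 7 cell lines: each point is 1 line, with GM07029 in blue, GM10835 in red, GM12813 in green and the other 4 in grey, and each black bar is the mean of the 7 lines. Glycolysis, HLA class II and histone genes lie lowest (list medians -1.21, -1.11 and -0.81) and immediate early genes highest (0.39). For histones GM10835 lies apart from the other lines at -0.08. Without centring all lists but glycolysis, HLA class II and histones lie above 0. With the trend of the ratio with signal removed, histones (-0.43) lie above cytosolic ribosomal proteins (-0.51) and oxidative phosphorylation (-0.44).

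The second comparison asked which transcripts differed in their ratio between GM07029, GM10835 and GM12813, the lines with replicate cultures. G0S2, an inhibitor of lipid breakdown, had the widest range. Its ratio was -0.40 ± 0.27 (SD, n = 3 cultures) in GM07029, 2.44 ± 0.21 in GM10835 and 0.73 ± 0.17 in GM12813 (adjusted p = 4.02e-05). Its nascent RNA differed 3.73 log2 units between lines and its total RNA 0.82, but that total RNA (6.07, 6.89 and 6.46) lay at or near background, so the size of the ratio range is uncertain. Most other genes with wide ranges differed more in total than in nascent RNA, though many of them also passed the test in nascent RNA. GOT2, the mitochondrial aspartate aminotransferase, had ratios of 0.75 ± 0.20, -0.30 ± 0.04 and 1.81 ± 0.33 in the same order (adjusted p = 0.000152). Its total RNA differed by 2.07, while its nascent RNA levels lay within 0.05 and did not pass the test (adjusted p = 0.755). The iron-sulphur protein CISD1 (total 1.92, nascent 0.10) and the calcium-binding protein S100A13 (total 2.22, nascent 0.28) were alike in this, as were EI24, MYL6, RAP1B, MKRN1 and RPS27L, none of which passed the test in nascent RNA. Absence of a call there does not show that the levels were equal.

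The ubiquitin-like modifier NEDD8 had ratios of -0.54 ± 0.40, -2.11 ± 0.22 and 0.50 ± 0.21, with total RNA ranging over 3.81 and nascent RNA over 1.23. The prion protein gene PRNP ranged over 2.44 (1.04 ± 1.15, 0.22 ± 0.30 and 2.66 ± 0.15), with a wide spread among the GM07029 cultures and a total RNA below background in GM07029 and GM12813. Total RNA was also below background in at least 1 line for CCNQ, H2BC3, RAP1B and PLAAT4. The signalling adaptor HCST (-1.08, -2.82 and -0.57), the membrane-remodelling protein CHMP2A (-0.15, -1.36 and 0.94), the histone chaperone NAP1L1 (-0.67, -1.79 and 0.38) and the mitochondrial RNA-binding protein SLIRP (0.38, -0.63 and 1.52) had their lowest ratio in GM10835 and their highest in GM12813. The same order of line means held for PEBP1 (range 2.10), PLAAT4 (2.02), ATP5MJ (1.86), TIMP1 (1.83), RPF2 (1.83), ARLN (2.50), CCNQ (2.23), CISD1 (1.93) and DYNLL1 (1.85). In the pairwise contrasts GM10835 and GM07029 did not differ past the threshold for CISD1 (adjusted p = 0.80), DYNLL1 (0.698), ARLN (0.224), ATP5MJ (0.176), RPF2 (0.110) and CCNQ (0.0981). Nor did GM12813 and GM07029 for HCST (0.0636) and TIMP1 (0.184). Only G0S2, the histone H2BC3 (highest in GM10835, range 2.16) and S100A13 (highest in GM07029, 2.08) of the 24 did not have their highest ratio in GM12813. The pairwise contrast of S100A13 between GM07029 and GM12813 did not pass (adjusted p = 0.675). Cultures of GM07029 also differed among themselves: ATP5MJ stood at -0.22, -1.52 and -1.54, RPS27L at -0.15, -2.23 and -1.24 and MYL6 at -0.75, -2.46 and -1.84. Of the 24 genes, only MKRN1 did not have replicate 1 as the GM07029 culture nearest to GM12813. With a one-way analysis of variance per cluster, the test that the series' design names, PRNP, H2BC3, RAP1B, RPS27L, MYL6, ATP5MJ and DYNLL1 no longer passed (adjusted p from 0.0563 to 0.0808).

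**Figure D2:**
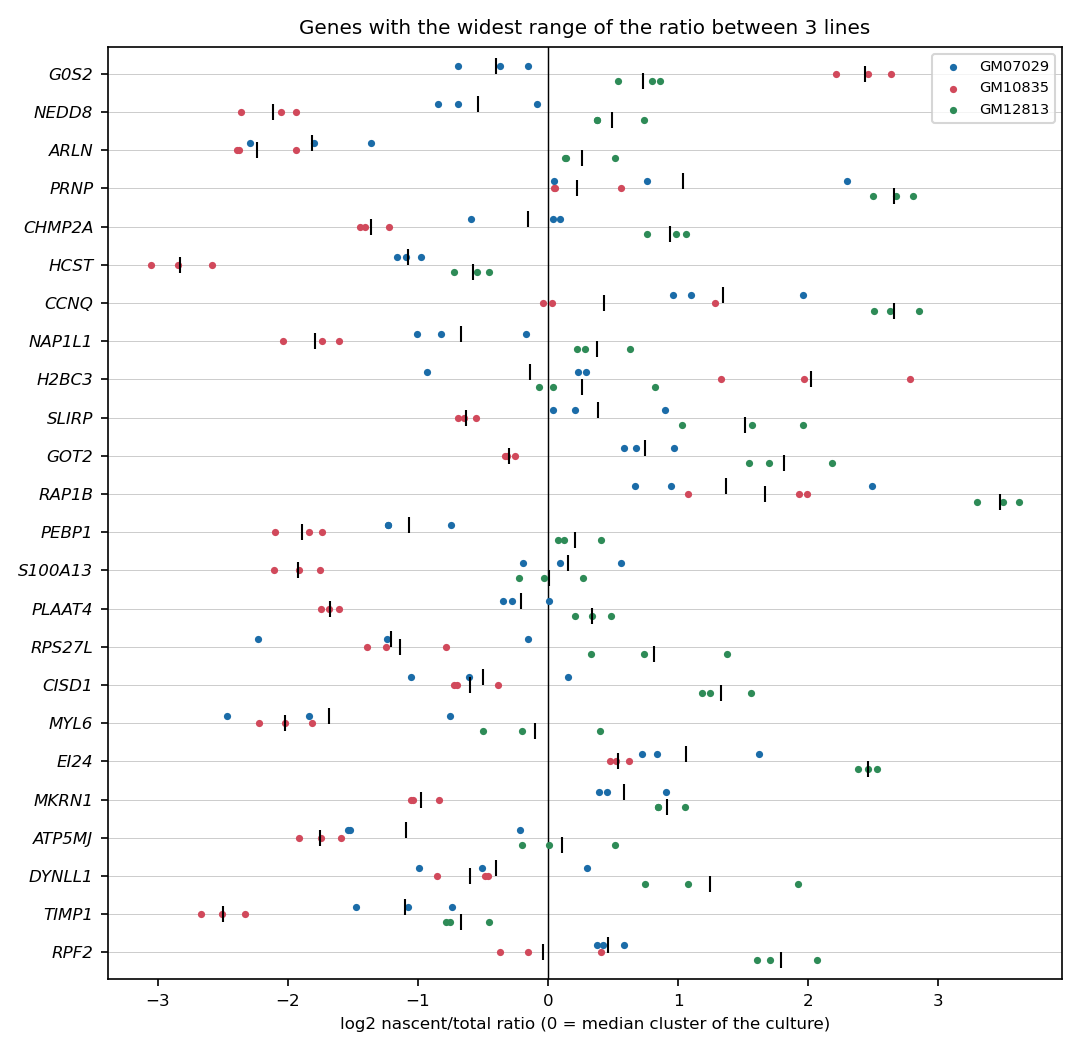
Log2 nascent/total ratio (horizontal axis, relative to the median cluster) of the 24 genes with the widest range of line means (vertical axis): each point is 1 culture, with GM07029 in blue, GM10835 in red and GM12813 in green, and each black bar is the mean of 3 cultures of a line. G0S2 is highest in GM10835 (2.44), and GOT2 has means of -0.30 in GM10835, 0.75 in GM07029 and 1.81 in GM12813 without overlap of their cultures.

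The ratio differed between the 3 lines for 3595 clusters (25.4%), with a median range of 0.66 and a range of at least 2-fold for 660. It was higher in GM10835 than in GM07029 for 1084 clusters and lower for 880, higher in GM12813 than in GM07029 for 695 and lower for 125, and higher in GM12813 than in GM10835 for 1798 and lower for 1474. The count changed with the arrays used: with only the first technical run of GM12813 it was 2140, and leaving out 1 culture at a time gave 1806 (without GM10835 replicate 3) to 5063 (without GM07029 replicate 1). Using only the second technical run of GM12813 replicate 3, a setting added after the data were seen, gave 3521. In each pairwise contrast the majority stayed on the same side under other scalings, but the counts moved. With quantile normalization they were 1228 and 968, 845 and 295, and 1846 and 1637, in the order above. Without centring they were 1198 and 551, 574 and 49, and 1387 and 1320. Line and the handling of its cultures cannot be told apart, since the labels name no batch, day or scan.

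Histone genes separated GM10835 from both other lines. Their ratio was higher in GM10835 than in GM07029 for 34 of 44 and lower for 0, with a median difference of 0.83 (adjusted p = 6.4e-21, and adjusted p = 0.134 with an estimated correlation). In GM12813 it was lower than in GM10835 for 32 and higher for 0 (median -0.80, adjusted p = 3.25e-19, and adjusted p = 0.134 with an estimated correlation). The F test called 34 of the 44 (38 adjusted over the list alone). H2BC3 differed by 2.16 ± 0.40 (standard error) and -1.76 ± 0.40 in these contrasts, H3C1 by 1.51 ± 0.17 and -1.62 ± 0.17, H2BC4 by 1.47 ± 0.21 in the first and H2BC26 by -1.46 ± 0.20 in the second. Immediate early genes went the same way: 11 of 32 rose from GM07029 to GM10835 (median 0.41, adjusted p = 1.91e-07), led by the G-protein regulators RGS2 (1.08 ± 0.17) and RGS1 (0.86). In GM12813, 15 were lower than in GM10835 (median -0.40, adjusted p = 1.08e-07), led by ZFP36 (-0.80), the phosphatase DUSP2 (-0.77) and IER3 (-0.75). With an estimated correlation both had adjusted p = 0.134, and the F test called 17 (20 adjusted over the list alone).

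Genes of the respiratory chain and ATP synthase went the opposite way. In GM10835, 21 of 55 had a lower ratio than in GM07029 and 0 a higher one (median -0.44, adjusted p = 1.33e-12, and adjusted p = 0.409 with an estimated correlation). In GM12813, 37 had a higher ratio than in GM10835 and 0 a lower one (median 0.69, adjusted p = 8.77e-17, and adjusted p = 0.271 with an estimated correlation), and 8 a higher ratio than in GM07029 (median 0.17, adjusted p = 0.0061, and adjusted p = 0.767 with an estimated correlation). ATP5MJ (1.86 ± 0.31), SDHD (1.69 ± 0.45) and COX7A2 (1.62 ± 0.20) differed most between GM12813 and GM10835, and NDUFA7 (-1.01 ± 0.11), NDUFV1 (-0.99) and COX6C (-0.93) between GM10835 and GM07029. The F test called 36 of the 55 (42 adjusted over the list alone). Mitochondrial ribosomal proteins followed, with 14 lower and 1 higher of 63 in GM10835 against GM07029 (median -0.18, adjusted p = 0.00125, and 0.767 with an estimated correlation). Against GM10835, GM12813 had 29 higher and 3 lower (0.35, adjusted p = 1.15e-06, and 0.767 with an estimated correlation), and against GM07029 6 higher (0.21, adjusted p = 0.0082, and 0.801 with an estimated correlation). MRPL23 (-1.18), MRPL21 (-1.13 and 1.53), MRPS17 (1.44) and MRPS14 (1.01) were among them. The proteasome had 7 lower of 33 (-0.18, adjusted p = 0.0013, and 0.767 with an estimated correlation), 18 higher (0.49, adjusted p = 1.94e-06, and 0.767 with an estimated correlation) and 6 higher (0.18, adjusted p = 0.00836, and 0.767 with an estimated correlation) in the same 3 contrasts. PSMB7 (-1.05 and 1.31), the immunoproteasome subunit PSMB8 (-0.96), PSME2 (1.37) and PSMB1 (0.80) led. The F test called 31 and 19 (36 and 22 adjusted over the list alone). Scaling the ratios to one interquartile range, a setting added after the data were seen, shrank the medians between GM10835 and GM07029 to -0.29 for oxidative phosphorylation and to -0.09 for mitochondrial ribosomal proteins and for the proteasome. Without centring the last 2 stood at -0.12 and -0.11.

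Cytosolic ribosomal proteins had 6 lower of 23 in GM10835 than in GM07029 (median -0.21, adjusted p = 0.0161, and 0.252 with an estimated correlation), among them RPS15A (-1.01), and 9 higher in GM12813 than in GM10835 (0.33, adjusted p = 0.00587, and 0.165 with an estimated correlation), among them RPL4 (1.30), RPL22 (1.30) and RPS27L (1.95), a p53-induced relative of a ribosomal protein. Translation factors had 10 higher of 34 in GM12813 than in GM10835 (0.27, adjusted p = 0.0061, and 0.767 with an estimated correlation), with the cap-binding EIF4E at 1.26 and EEF1AKMT1, a methyltransferase in the list by its name, at 1.19. The tRNA synthetases had 5 higher and 1 lower of 17 there (0.28, adjusted p = 0.0185, and 0.767 with an estimated correlation), with RARS1 at 0.90. Mitotic genes had 7 higher and 1 lower of 26 (0.32, adjusted p = 0.0106, and 0.767 with an estimated correlation), with TOP2A at 0.76, and 4 lower in GM10835 than in GM07029 (-0.13, adjusted p = 0.0197, and 0.767 with an estimated correlation), with CDC25C at -0.72. Zinc finger genes went with the histones, 53 of 266 being higher in GM10835 than in GM07029 and 0 lower (0.30, adjusted p = 9.59e-10, and 0.767 with an estimated correlation), with ZNF273 at 1.22, and 44 lower and 4 higher in GM12813 than in GM10835 (-0.24, adjusted p = 1.01e-07, and 0.767 with an estimated correlation). NF-kB targets had 5 higher and 1 lower of 26 (0.20, adjusted p = 0.00641, and 0.767 with an estimated correlation) and 9 lower and 2 higher (-0.20, adjusted p = 0.0082, and 0.767 with an estimated correlation) in these contrasts, with IRF1 at 0.75, ICAM1 at 0.68 and TNF at 0.70 and -0.95. The p53 targets had 5 higher and 2 lower of 20 (0.27, adjusted p = 0.0202, and 0.767 with an estimated correlation) and 5 lower and 1 higher (-0.20, adjusted p = 0.0246, and 0.767 with an estimated correlation), with MDM2 at 0.74 and BAX at 0.61 and -0.83. In GM12813 against GM07029, glycolysis was called lower with 1 called member of 14, PFKM at -0.42 (median of the differences per gene -0.13, adjusted p = 0.0306, and 0.767 with an estimated correlation). The median ratio of the glycolysis list itself did not fall, at -1.25 ± 0.13 in GM07029 and -1.24 ± 0.04 in GM12813 (SD, n = 3 cultures). B cell identity genes were called lower there with 2 of 27, TNFRSF13B at -0.52 and CIITA at -0.39 (median -0.09, adjusted p = 0.0202, and 0.767 with an estimated correlation). With the trend removed, 4 of the calls ended: cytosolic ribosomal proteins (adjusted p = 0.0548) and p53 targets (0.132) between GM10835 and GM07029, glycolysis (0.0544), and the tRNA synthetases (0.305). Their medians went from -0.21 to -0.14, 0.27 to 0.16, -0.13 to -0.16 and 0.28 to 0.11, so the glycolysis call ended without a smaller difference. With quantile normalization the median of the tRNA synthetases shrank to 0.14 and that of the cytosolic ribosomal proteins between GM10835 and GM07029 to -0.12. Ratios scaled to one interquartile range gave 0.15 for p53 targets in that contrast and -0.03 for glycolysis in GM12813 against GM07029. Without centring, mitotic genes stood at -0.06 in the former contrast and B cell identity genes at -0.06 in the latter. Technical duplicates of GM12813 differed by up to 0.21 in the median of zinc finger genes, 0.18 in that of tRNA synthetases and 0.21 in that of cytosolic ribosomal proteins, against line differences from GM10835 of -0.24, 0.28 and 0.33. The F test called 10 cytosolic ribosomal proteins, 13 translation factors, 7 tRNA synthetases, 9 mitotic genes, 59 zinc finger genes, 11 NF-kB targets, 8 p53 targets, 2 glycolysis genes and 8 B cell identity genes (11, 13, 7, 12, 44, 12, 8, 2 and 8 adjusted over the list alone).

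**Figure D3:**
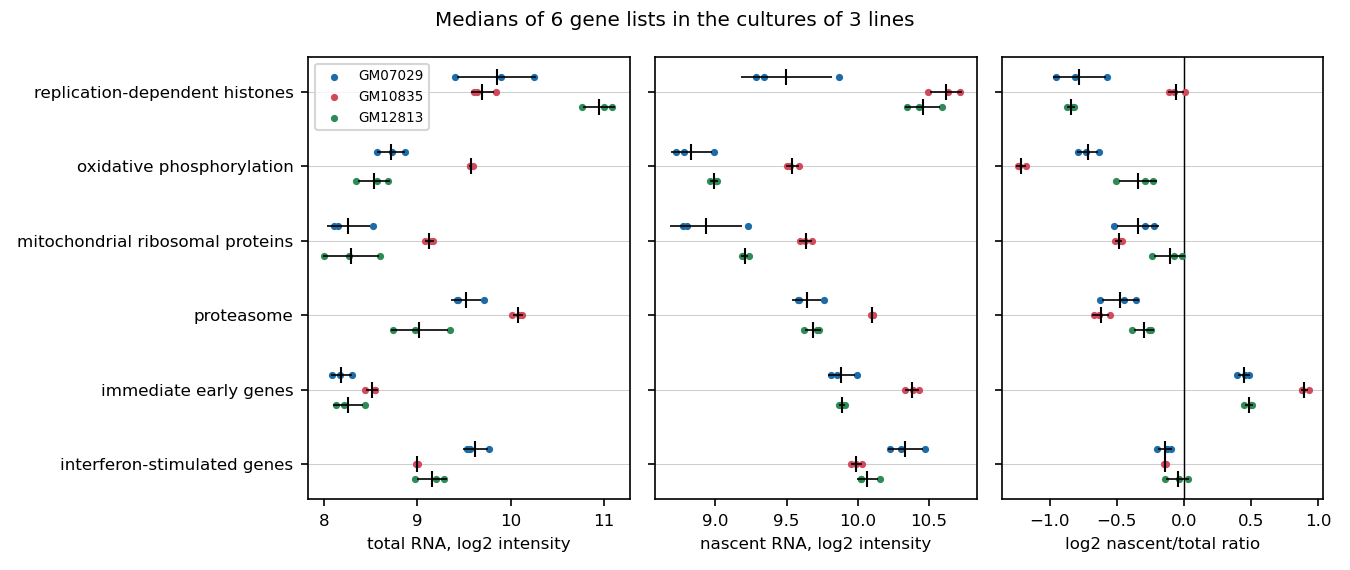
Median of 6 gene lists in total RNA (log2 intensity), nascent RNA (log2 intensity) and as nascent/total ratio (log2, relative to the median cluster), one panel each: points are the 3 cultures of GM07029, GM10835 and GM12813 and bars show the mean ± SD (n = 3). The histone ratio is -0.06 ± 0.06 in GM10835 against -0.78 ± 0.19 and -0.84 ± 0.03 in the other two, and the oxidative phosphorylation ratio is lowest in GM10835 (-1.21 ± 0.03), where its total RNA is highest (9.58 ± 0.02).

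Total RNA of the same cultures was compared to set steady-state levels beside the ratio. ND5, a mitochondrially encoded subunit of respiratory complex I, had the widest range of any named gene: 12.53 ± 0.16 (log2 intensity, SD, n = 3 cultures) in GM07029, 12.15 ± 0.14 in GM10835 and 4.29 ± 0.99 in GM12813 (adjusted p = 1.33e-07). The last value is below background, so that only a lower bound of the difference in signal is known. Nascent RNA stood at 12.43 ± 0.38, 12.35 ± 0.10 and 4.51 ± 0.59, the last also below background. ND6, another mitochondrial gene, looked up after its values were seen, stood at 9.63 ± 0.19, 8.42 ± 0.12 and 9.82 ± 0.08. Sequence variants of the donors were not analysed, so whether the probes of ND5 and of other genes read each donor alike is not known. The cytokine gene IL1A stood at 9.60 ± 0.12, 4.95 ± 0.22 and 7.87 ± 0.18, the receptor phosphatase PTPRK at 9.41 ± 0.23, 5.35 ± 0.07 and 8.21 ± 0.20, and F13A1, which encodes a subunit of coagulation factor XIII, at 10.21 ± 0.15, 7.33 ± 0.32 and 10.81 ± 0.17. APP, the amyloid precursor, was expressed in GM12813 (9.85 ± 0.04) and under background in GM07029 and GM10835 (5.83 and 5.98). The transcription factor LEF1 (6.01, 8.82 and 9.07) and the noncoding RNA FAM30A (5.61, 8.87 and 8.28) were low in GM07029. KLHL6, which acts in germinal centre B cells (7.29, 10.64 and 7.37), the chemokine receptor CCR9 (8.18, 9.84 and 6.19) and the protease MMP7 (10.23, 11.21 and 7.45) were highest in GM10835, as were GPM6A (range 3.76), PRNP (4.17), NEDD8 (3.81), NRIP1 (3.21), KRTAP17-1 (3.11) and ELAPOR2 (3.08). CHL1 (range 3.43), LIPH (3.49) and DPYD (3.13) were highest in GM07029 and the histone H1-1 in GM12813 (3.05). The pairwise contrast of CHL1 between GM07029 and GM12813 did not pass the threshold (adjusted p = 0.0561). Ranges that reach a level under 6.40 are uncertain in size, which of these 20 genes leaves NEDD8, MMP7, F13A1, CHL1 and KLHL6 above background in every line.

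**Figure D4:**
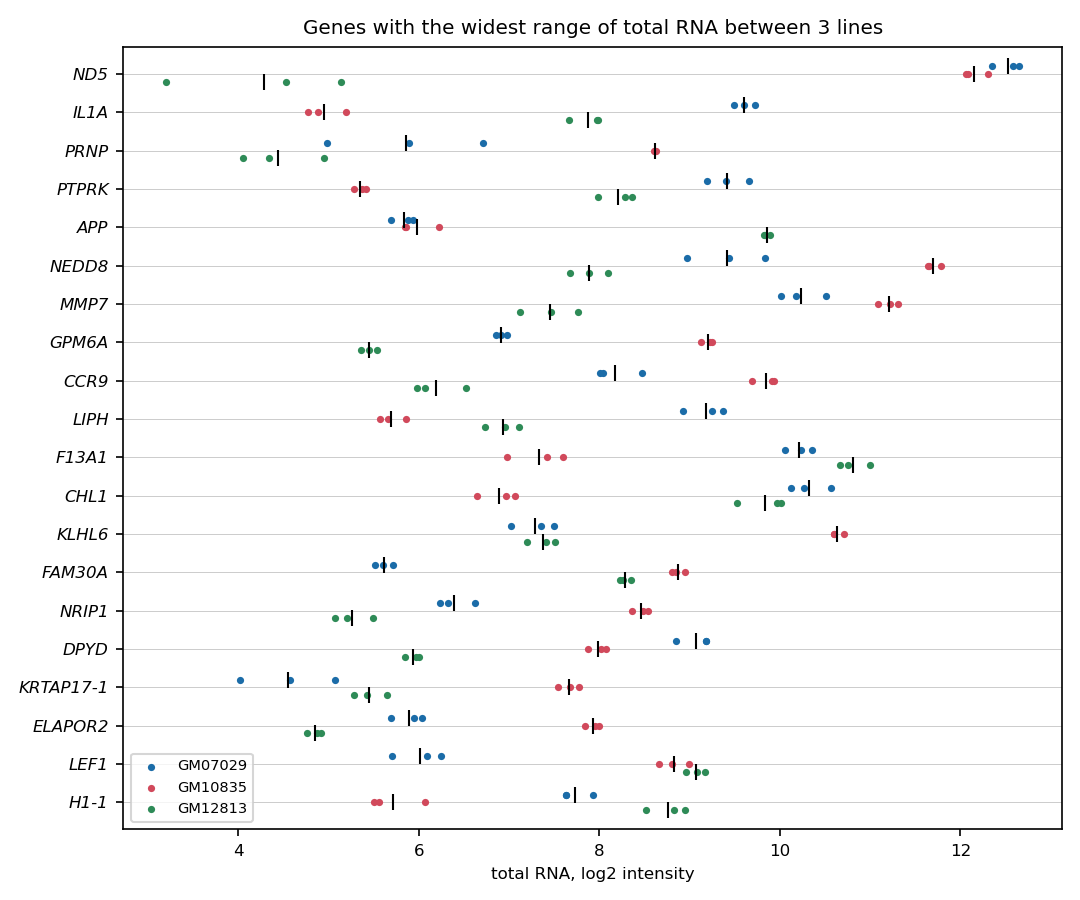
Total RNA level (log2 intensity, horizontal axis) of the 20 genes with the widest range of line means (vertical axis): each point is 1 culture, with GM07029 in blue, GM10835 in red and GM12813 in green, and each black bar is the mean of 3 cultures of a line. ND5 is near 12 in the first and second line (12.53 and 12.15) and at 4.29 in GM12813, and IL1A and PTPRK are lowest in GM10835 (4.95 and 5.35).

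Total RNA differed between the lines for 7962 clusters (56.2%), 1936 of them over at least 2-fold. GM10835 was higher than GM07029 for 4107 and lower for 2670, GM12813 was higher than GM07029 for 1534 and lower for 1927, and GM12813 was higher than GM10835 for 1775 and lower for 3592. These splits followed the scaling of the arrays: with quantile normalization within each fraction they were 3491 and 3708, 2486 and 2313, and 3334 and 3009, so the majority of every contrast turned. The medians of all clusters differed by 0.10, 0.01 and -0.05 in these contrasts. None of the called list differences in total RNA changed direction under these scalings.

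In total RNA, 9 lists were higher in GM10835 than in both other lines. Genes of oxidative phosphorylation were higher than in GM07029 for 46 of 55 and lower for 0 (median 0.92, adjusted p = 2.87e-11, and 0.804 with an estimated correlation), and 49 were lower and 0 higher in GM12813 than in GM10835 (-1.14, adjusted p = 4.6e-15, and 0.804 with an estimated correlation). NDUFC1 (1.75 ± 0.13), NDUFA2 (1.74) and COX6B1 (1.58) led the first contrast, and ATP5MJ (-2.39 ± 0.28), NDUFA1 (-2.12) and COX6C (-2.08) the second. Mitochondrial ribosomal proteins were higher for 48 of 63 and lower for 0 (0.69, adjusted p = 5.13e-09, and 0.804 with an estimated correlation), and then lower for 48 and higher for 1 (-0.66, adjusted p = 7.4e-10, and 0.804 with an estimated correlation), with MRPL51 at 1.70 and -1.89. The proteasome had 24 higher and 2 lower of 33 (0.59, adjusted p = 0.000235, and 0.838 with an estimated correlation) and 27 lower and 1 higher (-0.88, adjusted p = 2.25e-07, and 0.804 with an estimated correlation), with PSMB3 at 2.08 and -2.06. Cytosolic ribosomal proteins had 13 higher and 0 lower of 23 (0.55, adjusted p = 0.00544, and 0.509 with an estimated correlation) and 15 lower and 1 higher (-0.70, adjusted p = 0.000358, and 0.377 with an estimated correlation), with RPS15A at 2.57 and RPL22 at 1.39 and -1.76. The tRNA synthetases had 12 higher and 1 lower of 17 (0.49, adjusted p = 0.00274, and 0.829 with an estimated correlation) and 13 lower and 0 higher (-0.57, adjusted p = 0.000338, and 0.804 with an estimated correlation), with SARS1 at 0.99 and -1.06. Translation factors had 17 higher and 2 lower of 34 (0.39, adjusted p = 0.029, and 0.947 with an estimated correlation) and 19 lower and 2 higher (-0.44, adjusted p = 0.00103, and 0.829 with an estimated correlation), with EIF3K at 1.43 and -1.47. Glycolysis had 9 higher and 0 lower of 14 (0.47, adjusted p = 0.00103, and 0.804 with an estimated correlation) and 7 lower and 0 higher (-0.30, adjusted p = 0.0152, and 0.854 with an estimated correlation), with ALDOC at 1.07 and -0.61. With quantile normalization the medians of the last contrast shrank more than 1.5-fold for the tRNA synthetases (-0.34), translation factors (-0.25) and glycolysis (-0.16).

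Heat shock and unfolded protein response genes had 12 higher and 1 lower of 20 than GM07029 (median 0.68, adjusted p = 0.00421, and 0.804 with an estimated correlation), and GM12813 had 14 lower and 1 higher than GM10835 (-0.55, adjusted p = 0.000235, and 0.804 with an estimated correlation). The stress factor DDIT3 (CHOP) differed by 1.97 and -2.04, CHAC1 by 1.70 and the chaperone HSPA5 (BiP) by -1.91. Plasma cell genes had 11 higher and 2 lower of 16 (0.74, adjusted p = 0.0084, and 0.804 with an estimated correlation) and 9 lower and 3 higher (-0.61, adjusted p = 0.012, and 0.804 with an estimated correlation), led by MZB1 (2.31 and -1.85), SSR4 (1.96 and -2.41) and SEC11C (-2.04). GM07029 had the highest levels of interferon-stimulated genes and p53 targets. Of 30 interferon-stimulated genes, 18 were lower and 6 higher in GM10835 (-0.53, adjusted p = 0.000161, and 0.804 with an estimated correlation) and 18 lower and 1 higher in GM12813 (-0.48, adjusted p = 1.66e-07, and 0.804 with an estimated correlation). IFIT3 differed by -2.27 ± 0.09 and IFIT1 by -2.04 ± 0.11 in GM10835, and the RNA sensor RIGI by -1.47 ± 0.15 in GM12813. Of 20 p53 targets, 13 were lower and 1 higher in GM10835 (-0.50, adjusted p = 0.000252, and 0.804 with an estimated correlation) and 12 lower and 0 higher in GM12813 (-0.57, adjusted p = 1.66e-07, and 0.804 with an estimated correlation), with MDM2, the ligase that limits p53, at -1.66 and -1.37. With quantile normalization the medians between GM12813 and GM10835 shrank to -0.35 for the unfolded protein response and -0.39 for plasma cell genes.

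Histones were higher in the total RNA of GM12813, for 32 of 44 against GM07029 with 1 lower (median 0.65, adjusted p = 2.06e-13, and 0.804 with an estimated correlation) and for 34 against GM10835 with 0 lower (0.71, adjusted p = 4.6e-15, and 0.804 with an estimated correlation), with H1-1 at 3.05 ± 0.17 and H3C10 at 1.31 ± 0.16. The median level of the list in GM12813 (10.98) lay within that of the lines with 1 culture (10.83 to 11.21). In GM07029 (9.87) and GM10835 (9.75) it lay below them. DNA replication genes were higher in GM10835 than in GM07029 for 15 of 25 and lower for 2 (0.35, adjusted p = 0.0256, and 0.9503 with an estimated correlation), with MCM5 at 1.32, and higher in GM12813 than in GM07029 for 6 and lower for 2 (0.22, adjusted p = 0.0384, and 0.958 with an estimated correlation). Zinc finger genes were lower in GM10835 than in GM07029 for 74 of 266 and higher for 28 (-0.15, adjusted p = 0.000161, and 0.933 with an estimated correlation), and higher in GM12813 than in GM10835 for 66 and lower for 15 (0.13, adjusted p = 1.45e-05, and 0.885 with an estimated correlation). HLA class II genes were higher in GM12813 than in GM07029 for 4 of 7 and lower for 0 (0.33, adjusted p = 0.029, and 0.804 with an estimated correlation), among them their activator CIITA at 0.77. Proteasome subunits were lower there for 8 of 33 (-0.12, adjusted p = 0.0477, and 0.981 with an estimated correlation), and markers of fibroblasts and epithelia were higher with 1 called gene of 7, PDGFRB at 0.60 (0.23, adjusted p = 0.0423, and 0.804 with an estimated correlation). The last pair of calls ended with the trend removed (adjusted p = 0.0619 and 0.107), where the proteasome median shrank to -0.06 and that of the markers stayed at 0.22. None of the 31 called list differences in total RNA held with an estimated correlation. The F test called 49 oxidative phosphorylation genes, 54 mitochondrial ribosomal proteins, 30 proteasome subunits, 38 histones, 25 interferon-stimulated genes, 16 p53 targets and 115 zinc finger genes in total RNA (50, 55, 31, 38, 25, 16 and 105 adjusted over the list alone). For cytosolic ribosomal proteins, tRNA synthetases, translation factors, glycolysis, heat shock and unfolded protein response, plasma cell, DNA replication and HLA class II genes it called 19, 14, 23, 10, 17, 14, 17 and 6 (19, 15, 23, 10, 17, 14, 17 and 6 adjusted over the list alone).

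Nascent RNA differed between the lines for 8019 clusters (56.7%), 862 of them over at least 2-fold. After ND5, the widest ranges belonged to FAM30A (5.73 ± 0.47, 10.26 ± 0.12 and 9.32 ± 0.02 in GM07029, GM10835 and GM12813; SD, n = 3), CCR9 (9.27, 11.39 and 7.31), PTPRK (9.76, 5.75 and 8.50), IL1A (10.40, 6.48 and 9.25), F13A1 (10.05, 6.59 and 10.39) and G0S2 (lowest in GM07029 at 6.44 ± 0.34, highest in GM10835 at 10.16 ± 0.06). The guidance ligand EFNA5, the transcriptional coregulator NRIP1 and the proteoglycan GPC4 ranged over 3.50, 3.47 and 3.45. FAM30A, PTPRK, EFNA5 and GPC4 were below background in the line with the lowest level. GM10835 was higher than GM07029 for 5885 clusters and lower for 1940, and GM12813 was higher than GM10835 for 1557 and lower for 4586. With quantile normalization these majorities were 4045 against 3578, and 3006 against 3137, and the median of all clusters between GM10835 and GM07029 went from 0.16 to 0.01.

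Of the clusters whose total RNA differed, 72.4% also differed in nascent RNA and 37.2% in the ratio. The tests differ in power: of genes simulated with a log2 difference of 0.5, that of nascent RNA called 62.7% and that of the ratio 20.9%. The shares therefore do not show how often a difference lies in nascent RNA and how often in the ratio. Total and nascent calls shared 5763 clusters, where independent lists would share 4511, and 3706 of these were not called in the ratio. Ratio and total RNA shared 2964, against 2022 for independent lists, although both contain the same total RNA arrays. There were 109 clusters called in the ratio alone, and 2057 in all 3 measures. Few calls in the ratio alone were bound to follow, since the ratio is made from both levels. PTPRK, CHL1 and ELAPOR2 were cases of a large difference in both levels (3.08 to 4.06) with a ratio range of 0.04 to 0.09, which did not pass the test, although PTPRK and ELAPOR2 were below background in the total RNA of at least 1 line.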

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

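The splits of lines and cultures into other groups and the removal of the trend of the ratio with signal were chosen before these results were seen (the trend removal after a first look at the data), and the search for named handling batches after. A value counts as apart by its gap relative to the range of the 7 lines, at a limit that chance passes in about 1 in 20 groups of normally distributed values; this rate was not estimated from these data. Of 97 named genes 4 had 1 line far from the other 6, and of 25 lists 3. Of these 7 cases 5 were in GM10835 and 2 in GM12815.

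The histone list had a median ratio of -0.084 in GM10835 and of -1.11 to -0.81 in the other 6 lines. H4C1 went with it, at -0.96 in GM10835 against -2.14 to -1.82. H2BC11, which had a high ratio in every line, stood at 2.33 in GM10835 against 1.46 to 1.73. GM10835 also stood apart for p53 targets (0.42 against 0.01 to 0.13) and for CD74, the chaperone of HLA class II (-0.57 against -1.54 to -1.13). GM12815, which had 1 culture, stood apart for the initiation factor subunit EIF3L (-2.67 against -1.97 to -1.74) and for B cell identity genes (-0.72 against -0.34 to -0.12). The cause was not tested.

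The ratio differed between GM07029, GM10835 and GM12813 for 3595 clusters, and 32 genes named for their ratio over all lines were among them (adjusted p from 0.0014 to 0.0426). The order of lines is that of their means, not of pairwise tests, and values in brackets are ranges of these means in log2 units. Highest in GM12813 and lowest in GM10835 were DNAJA1 (1.28), APOBEC3H (1.25), HSPA5 (1.03) and NDUFB5 (0.86). Highest in GM12813 and lowest in GM07029 were RPL11 (0.96), RPS24 (0.93), EIF5B (0.90) and TNIP1 (0.54). Highest in GM07029 and lowest in GM10835 were PSMB6 (0.82), ALDOC (0.65), EBI3 (0.57), RPL18 (0.50) and ATP5F1C (0.47). In GM10835 the ratio was highest, and in GM12813 lowest, for H4C1 (1.102), MS4A1 (0.97), TNF (0.95), H2AC8 (0.78), LTA (0.74), LSS (0.70), IER2 (0.67), CD74 (0.67), HLA-DOA (0.61), PDK1 (0.53), MYC (0.50), FOS (0.48) and CR1 (0.43). Lowest in GM07029 and highest in GM10835 were JCHAIN (0.87), ATF3 (0.65), TNFRSF10B (0.62), ZNF263 (0.55), JUN (0.52) and UPF1 (0.49).

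Other signs and other groupings were tried to see how many calls they gave. Ratios of different lines had a mean correlation of 0.797, so turning the sign of some lines cancels the profile they share. Few calls were bound to follow, and the sign splits cannot decide on chance. Over 7 lines, 1 of 64 ways of setting the signs gave as many calls as the real one (8989, highest other 0 by limma at the adjusted threshold; at unadjusted p under 0.05 the real signs gave 9425 and the highest other 6057). Between 3 lines, 1 of 100 groupings of the 9 cultures, the real one, gave as many: 3595 for the ratio (highest other 1673), 7962 for total RNA (3863) and 8019 for nascent RNA (5715). Cultures of a line thus went together more than those of the other groupings drawn, which shared handling would also give. With the trend of the ratio with signal removed the ratio count was 3911, so that trend does not make it. The labels name 0 batch characteristics, and a line cannot be told apart from the handling of its cultures, which may add to every difference between lines.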

How the results depend on the processing

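Settings added after the data were seen were the trend of the ratio with signal removed, the second technical run only for GM12813 replicate 3 (3521 calls of the ratio between 3 lines) and ratios scaled to one interquartile range (2556). The ratio between 3 lines, called for 3595 clusters, was weaker with no filter (2006), with the first technical run only (2140) and with a one-way analysis of variance per cluster (2274). Leaving out 1 culture at a time gave 1806 to 5063: 1806 without GM10835 replicate 3, 1947 and 2082 without GM12813 replicate 2 and 3, 2236 and 2351 without GM10835 replicate 2 and 1. The cause was not tested. A replicate block gave 2460, and the numbers do not pair the samples across lines. Over 7 lines, treat against an absolute log2 ratio of 0.5 called 3235, and leaving out 1 line gave 8318 to 8951. With no filter 21754 clusters were tested. With an estimated correlation camera called 0 lists over 7 lines and 0 between 3 lines in the ratio, 0 in total RNA and 0 in nascent RNA (unadjusted p under 0.05 for 1 of 25, 8 of 75, 2 of 75 and 6 of 75), where fry called 17 over 7 lines. Ratios that turned positive were MALAT1 (0.25), TUG1 (0.066) and NFKBIA (0.55) with the trend removed, and MALAT1 (0.40), TUG1 (0.47), CD6 (0.38), MNDA (0.48), MUC1 (0.52), NFKBIA (0.70) and TUBB (0.0099) without centring.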

Other observations

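The list contrasts in nascent RNA below were added after the data were seen, as were the 3 tests on oxidative phosphorylation and the 2 on the smaller differences in nascent RNA. The comparison of low, middle and high ratios was chosen before. Of 20 p53 targets 16 were lower in GM12813 than in GM07029 and 0 higher (median -0.56, adjusted p = 1.05e-16, and 0.149 with an estimated correlation), with TP53INP1 at -1.05 ± 0.11 (standard error) and SESN1 at -0.88. Of 30 interferon-stimulated genes 16 were lower in GM12813 than in GM07029 and 0 higher (-0.26, adjusted p = 5.87e-14, and 0.149 with an estimated correlation), with the RNA sensor RIGI at -1.10. In GM10835 against GM07029, 17 interferon-stimulated genes were lower and 4 higher (-0.34, adjusted p = 1.05e-08, and adjusted p = 0.304 with an estimated correlation), with the antiviral RSAD2 at -2.32.

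In the nascent RNA of GM10835, mitochondrial ribosomal proteins were higher than in GM07029 for 60 of 63 and lower for 0 (median 0.58, adjusted p = 5.47e-08, and 0.493 with an estimated correlation), oxidative phosphorylation for 48 of 55 and lower for 0 (0.52, adjusted p = 7.03e-06, and 0.493 with an estimated correlation). Immediate early genes were higher for 22 of 32 and lower for 2 (0.55, adjusted p = 0.00161, and 0.509 with an estimated correlation), with PIM1 at 1.53, and JUN fell from GM10835 to GM12813 by 1.49. Plasma cell genes were higher for 13 of 16 and lower for 2 (0.86, adjusted p = 0.00147, and 0.509 with an estimated correlation), with JCHAIN at 2.27, and unfolded protein response genes for 13 of 20 and lower for 1 (0.70, adjusted p = 0.00236, and 0.493 with an estimated correlation), with CHAC1 at 2.37. Histones were higher than in GM07029 for 38 of 44 in GM10835, with 1 lower (0.79, adjusted p = 1.86e-05, and 0.599 with an estimated correlation) and for 35 in GM12813, with 0 lower (0.70, adjusted p = 5.79e-16, and 0.493 with an estimated correlation). NF-kB targets were lower in GM12813 than in GM10835 for 18 of 26 and higher for 0 (-0.37, adjusted p = 0.000391, and adjusted p = 0.519 with an estimated correlation), with CCR7 at -0.96. Quantile normalization shrank the medians between GM10835 and GM07029 for mitochondrial ribosomal proteins (0.58 to 0.37), oxidative phosphorylation (0.52 to 0.34) and immediate early genes (0.55 to 0.36), and that of NF-kB targets to -0.24, without a change of sign, and that of interferon-stimulated genes between GM10835 and GM07029 grew to -0.51. It took the median of all clusters between GM10835 and GM07029 from 0.16 to 0.01.

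Genes of oxidative phosphorylation had a lower ratio in GM10835 than in GM12813 by a median of 0.69. The largest difference between arrays of the same RNA was 0.22, over 3 duplicate pairs that were all of GM12813. Differences of that size are too small to make it, but GM10835 had no technical duplicates, so its variation between arrays is not known. For zinc finger genes the duplicates differed by up to 0.21, against a line difference of -0.24. Without the total RNA array of GM12813 that stands apart the difference was 0.75, and with the trend of the ratio with signal removed it was 0.63. None of these 3 checks removed the difference, with variation between arrays known for GM12813 only. Handling of the cultures could still contribute and has no test here.

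Line differences were smaller in nascent than in total RNA: with covariances between different cultures, which leave out array noise, the ratio of their SDs was 0.827 for GM10835 and GM07029, 0.677 for GM12813 and GM07029 and 0.728 for GM12813 and GM10835. Array noise shared by the ratio and total RNA does not account for this, since the highest of these ratios over all choices of cultures was 0.886, below 1. Compression of the nascent arrays over their whole range would lower their SD alike, and the lowest ratio of nascent to total SD among 9 cultures was 0.885. That value lies above the ratio of each pair. For GM10835 and GM07029 it lies within the spread over choices of cultures (0.777 to 0.886). Every choice lay below it for GM12813 and GM07029 (highest 0.838) and for GM12813 and GM10835 (highest 0.787). The test asked for this in every pair of lines. It also takes the true levels of nascent and total RNA to be equally spread, which is not known. It therefore cannot decide on compression, which stays open for every pair.

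The share of clusters whose total RNA differed was not larger where the ratio was high: it was 66.6% for the lowest ratios, 48.5% for middle ones and 53.7% for the highest, a quotient of highest over lowest of 0.806, with 0 of 4 levels of signal having a quotient over 1.1. Ratio groups and signal levels came from the 4 lines with 1 culture. From low to high signal the share was 51.2%, 62.1%, 65.8% and 70.7% for the lowest ratios. For the highest ratios it was 42.5%, 55.3%, 61.8% and 71.4%, so the gap closed as signal rose.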
